A study of Mus musculus with 3 samples.

How the data were processed

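The series holds 3 single-cell RNA sequencing libraries of C57BL/6 mice carrying tumours of KPC63, a pancreatic tumour cell line, in the hind leg. Per the labels' protocols, 1000000 cells were injected under the skin, and the lymph nodes draining the tumour were pooled from 3 mice in each treatment group. One library came from control mice, which the series text describes as given isotype antibody, one from mice whose tumours received 10 Gy of photons, and one from mice given a combination immunotherapy whose antibodies are not named in the sources used here. Tissue was taken 16 days after irradiation. The tissue label names both tumour and draining lymph node, while the series text speaks of the lymph nodes alone, and the proportion in which tumour and node cells were mixed is not given in the sources used here.

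Per the labels' protocols, dissociated cells were frozen, thawed and loaded on the 10x Genomics Chromium platform with a target of 10000 cells and 50000 reads per cell on an Illumina NovaSeq. The protocol text names both a 3' and a 5' kit, and which of them was used is not given in the sources used here. Reads from the 5' end cover the variable segments of receptor transcripts, and these libraries had 0.902, 0.904 and 0.810 Trbv UMIs per 100 UMIs of Trbc1 and Trbc2 in control, photon and immunotherapy, a low level of the kind that reads from the 3' end give, although no library of known chemistry was set beside them. The authors' deposited matrices hold raw UMI counts per gene and cell barcode for 32285 genes, not normalised. Reads were processed with Cell Ranger 5.0.1 on genome build mm10, per the submitters' processing notes, and the annotation release is not given in the sources used here. The barcodes are those left by the authors' cell calling, since the lowest total in the deposited counts was 500 UMIs. Reads shared between near-identical copies of a gene, such as the immunoglobulin constant regions, the guanylate-binding proteins and the Tgtp pair, could have been split by the counting, and their levels are uncertain to that extent. Gene coordinates were taken by gene identifier from the GENCODE annotation of GRCm38, the assembly also called mm10.

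Cells were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. Doublets were called in each library with Scrublet in scanpy 1.11.5 with an assumed rate of 5% and were removed. Counts of the 12898 cells kept were scaled to 10000 per cell and log transformed. After mitochondrial genes and receptor variable segments were set aside, 2000 highly variable genes gave 30 principal components, and cells were joined to their 15 nearest neighbours and clustered with the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, random seed 7). All 3 libraries were clustered together without batch correction. This gave 17 clusters, and the T and NK clusters were clustered again into 13 subclusters. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

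Each cluster was named for the class with the highest mean log2 fold of its fixed markers, computed with 20 CPM added, where at least 3 of the markers were detected in 15% of its cells. A cluster with at least 2 proliferation genes among its top 10 was called cycling lymphocytes whatever its class score, which for this cluster of 248 cells was highest for plasma cells. The names are therefore read as B-like, epithelial-like and so on, and are written below without the ending. T subclusters were called CD4 or CD8 T where one receptor was detected at least 3 times as often as the other. A regulatory T (Treg), NK or gamma-delta name also needed a marker among the top 10 genes by fold, a rule set after the clusters were seen, and the remaining subclusters are given as T cells not resolved. Cells of the epithelial class carry keratins as the injected tumour cells would, but no sequence that marks the injected line was used.

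With 1 library per group there is no test, p-value or standard error in any comparison, and cells were not treated as replicates. For each class with at least 50 cells in both libraries compared, UMIs were summed over cells and expressed as CPM, counts per 1000000 of the class total, with exact 95% Poisson intervals. The log2 ratio of CPM has an exact conditional interval. Shares of cells have exact Clopper-Pearson intervals. All these intervals cover counting error only, and they leave out the spread between mice. Those of CPM and of its ratios also leave out the spread between cells. Where a count was 0, the ratio was computed against a floor of 3 counts and is given as a bound. A gene list is described by the median log2 ratio of its members with at least 20 UMIs over both libraries, with a 95% interval from 1000 bootstrap draws of the members, and by the percentile of that median among 10000 random lists of the same size drawn from genes of matched mean expression (the 100 nearest). The percentile describes these libraries and is no test of a treatment. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs, which left out 576 of the cells kept.

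The named genes followed a rule. In each comparison and in each of the 4 classes with the most cells, they were the 3 genes with the highest and the 3 with the lowest ratio among those with at least 100 UMIs over both libraries and at least 50 CPM in the higher one, leaving out predicted gene models, mitochondrial and ribosomal protein genes and receptor segments. To these were added the 2 highest and the 2 lowest members of each list that is described, and Pdcd1, Ctla4, Cd274, Lag3, Tigit, Havcr2, Foxp3, Gzmb, Ifng, Cdkn1a and Mki67 where they were detected. Some genes that the rule names are not reported here. This rule, the gene lists, the cell type markers, the filters and the alternatives not described as added were set before the data were examined.

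The steps were tested on simulated data drawn from the real class means and depths. Among 200 genes simulated at 4-fold in epithelial cells for photon against control, 100% came out in the right direction. Over the 10837 genes of that step the counting intervals held the simulated ratio for 95.3%. The simulated counts were Poisson draws, the model of the intervals, so a share near 95% was fixed in advance. It says nothing on spread between cells, which was not simulated. A list simulated at a log2 ratio of 1 came out at 0.98 and at percentile 100 of its random lists. For the same comparison it came out at 0.94 in B cells and 0.84 in macrophages, where the unchanged genes lay at -0.06 and -0.13, and for immunotherapy against control at 0.98, 0.94 and 0.81 in these 3 classes. Alternatives varied the clustering resolution, the number of variable genes, the cell filters, the doublet removal, the way cells were assigned to classes, the scaling of counts and the minimum for list members.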

Results

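Single-cell transcriptomes were collected from mice bearing subcutaneous KPC63 pancreatic tumours to describe the immune and tumour cells present after photon irradiation or combination immunotherapy. The design has 3 groups with 1 library each: control, photon (10 Gy) and immunotherapy. The libraries held 5978, 6071 and 6079 cell barcodes with 49001253, 61339171 and 45078333 UMIs, in that order. After the filters and removal of 45, 32 and 51 called doublets, 4702, 4092 and 4104 cells remained, with a median of 3399, 2626 and 4475 UMIs per cell. Values in brackets after a level, a share or a ratio are 95% intervals for counting error only, and after a list median they are 95% intervals over the list's members. At 100 UMIs the counting interval reached 21.6% above the value. Because each group has 1 library, every difference given below has no replicate check and describes these libraries.

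The cells fell into B, T and NK, epithelial, neutrophil, macrophage, fibroblast, dendritic and endothelial classes. B cells led by number in the control library and epithelial cells in the photon library. UMIs summed over a class ranged from 1323400 in photon B cells to 41035687 in photon epithelial cells among the B and epithelial classes, so photon B cell values are the less precise of these. Among the genes described below, Iigp1 (ENSMUSG00000054072) lies on chromosome 18 at 60376027 to 60392634 of GRCm38 and Cxcl9 (ENSMUSG00000029417) on chromosome 5 at 92321347 to 92328079. Igtp (ENSMUSG00000078853) lies on chromosome 11 at 58199556 to 58207591 and Cd274 (ENSMUSG00000016496) on chromosome 19 at 29367455 to 29388095. Epcam (ENSMUSG00000045394) lies on chromosome 17 at 87635979 to 87651129, Ptgs2 (ENSMUSG00000032487) on chromosome 1 at 150100031 to 150108227, and Cdkn1a (ENSMUSG00000023067) on chromosome 17 at 29090976 to 29100727. Foxp3 (ENSMUSG00000039521) lies on chromosome X at 7573644 to 7595245. All of these are annotated as protein-coding genes.

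The first question was which cells made up each library. B cells were 58.1% of control cells (56.7 to 59.5), 16.9% of photon cells (15.8 to 18.1) and 43.9% of immunotherapy cells (42.4 to 45.5). Epithelial cells, the class that carries the keratins of the injected tumour line, were 9.21% of control cells (8.40 to 10.1), 25.3% of photon cells (24.0 to 26.7) and 9.16% of immunotherapy cells (8.30 to 10.1). Neutrophils were 6.57% (5.88 to 7.32), 22.9% (21.7 to 24.3) and 10.1% (9.21 to 11.1), and macrophages 1.94% (1.56 to 2.37), 9.31% (8.44 to 10.2) and 1.95% (1.55 to 2.42), in the same order. T and NK cells were 21.2% (20.001 to 22.4), 18.1% (16.9 to 19.3) and 27% (25.7 to 28.4). Fibroblasts were 2.93% of photon cells (2.44 to 3.50) against 0.659% in control and 0.682% in immunotherapy.

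Because the tissue label names both tumour and lymph node, ratios between classes were also read. Photon macrophages numbered 0.368 per epithelial cell (0.326 to 0.414), against 0.210 in control (0.166 to 0.264) and 0.213 in immunotherapy (0.165 to 0.271). Neutrophils per epithelial cell were 0.714 in control (0.615 to 0.828), 0.906 in photon (0.829 to 0.991) and 1.10 in immunotherapy (0.958 to 1.27). Among lymphocytes, there were 3.46 B cells per CD4 or CD8 T cell in control (3.19 to 3.75), 1.34 in photon (1.20 to 1.51) and 2.48 in immunotherapy (2.27 to 2.70). The mitochondrial limit removed 20.6% of control, 32.1% of photon and 31.6% of immunotherapy barcodes. With all barcodes counted, the B share in immunotherapy lay -8.61 percentage points from control in place of -14.2, the T and NK share 2.22 in place of 5.89, and the neutrophil share 1.79 in place of 3.54. Under the same setting the photon neutrophil difference was 10.9 in place of 16.4 points and the photon T and NK difference -5.48 in place of -3.10. The latter was -6.97 under a stricter cell filter, and the T and NK difference of immunotherapy was 3.37 there. With classes taken from each cell's own marker score, the macrophage difference of photon was 4.77 points in place of 7.38.

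**Figure D1:**
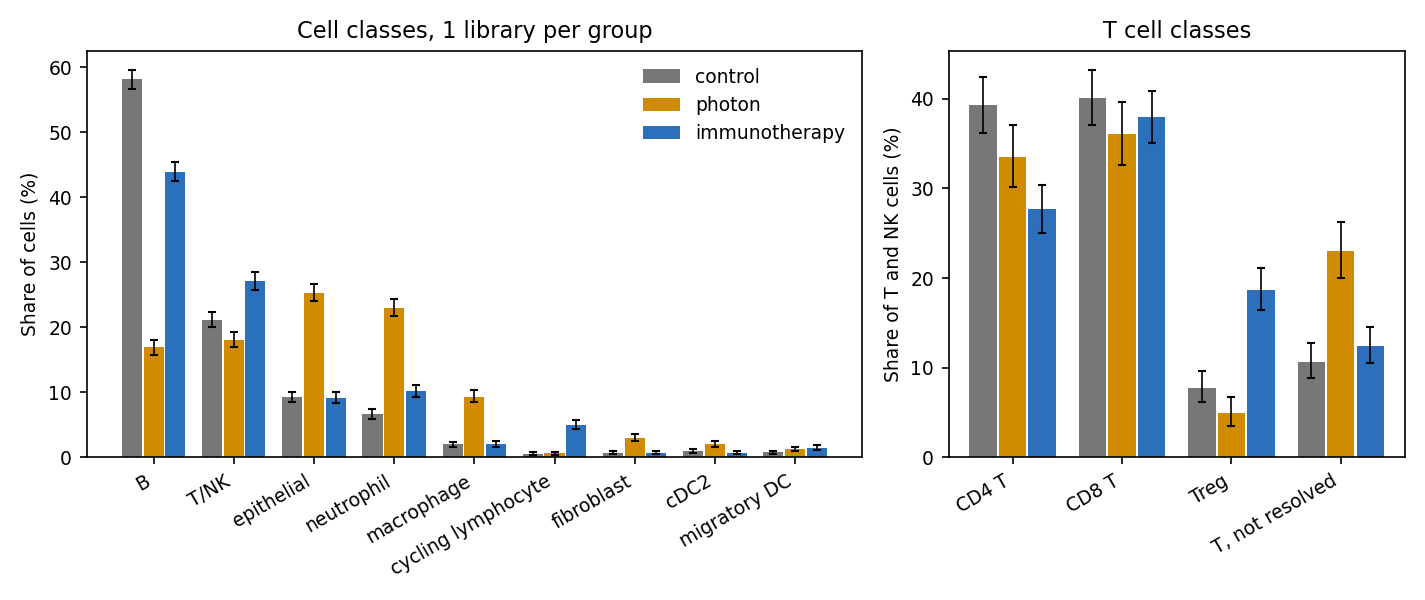
Shares of cells (%) in each class for control, photon and immunotherapy, at left among all cells and at right among T and NK cells; bars are 1 library each, starting at 0, and error bars are 95% Clopper-Pearson intervals for counting error. B cells stand at 58.1% in control and 16.9% in photon, and Treg cells at 18.6% of T and NK cells in immunotherapy.

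Compared with control, Treg cells, which restrain other T cells, were a larger share of the T and NK cells in immunotherapy. They were 18.6% of T and NK cells there (16.4 to 21.1) against 7.74% in control (6.16 to 9.58), a difference of 10.9 percentage points (8.06 to 13.7) that was 6.38 points when cells were clustered at resolution 2. CD4 T cells were 39.3% (36.2 to 42.4), 33.6% (30.2 to 37.1) and 27.7% (25 to 30.4) in control, photon and immunotherapy, and CD8 T cells 40.1%, 36.1% and 37.9%. The photon Treg share, 4.87% (3.43 to 6.68), lay below control, but this difference of -2.87 points had the opposite sign under 5 alternatives, so its direction was not resolved. The photon share was 8.89% against 9.41% in immunotherapy at resolution 2, and 22.6% against 24.3% under the stricter filter. With 4000 variable genes it was 16.7% against 21.4%, with doublets kept 17.3% against 21.2%, and by marker score 10.8% against 17.7%. How far the Treg share of immunotherapy exceeded that of photon was therefore not resolved. T cells not resolved into a class were 10.7% in control (8.80 to 12.7), 23% in photon (20.01 to 26.2) and 12.4% in immunotherapy (10.5 to 14.5). They included a subcluster of 35 cells (10, 9 and 16 in these libraries) led by the B cell genes Cd79a, Cd74, Igkc and Ms4a1, with no T cell marker among its 10 leading genes and a median of 6122 UMIs. Relative to the median cell of its own library, the median cell of this subcluster had 1.99 times the UMIs. Another unresolved subcluster of 186 cells (33, 117 and 36) scored highest for Treg cells but had no Treg marker among its 10 leading genes. Foxp3, the transcription factor that defines Treg cells, had a UMI in 4.42% of control (3.23 to 5.89), 5.68% of photon (4.13 to 7.60) and 11.4% of immunotherapy T and NK cells (9.63 to 13.5). In B cells, which should lack it, the shares were 0.146%, 0.145% and 0.444%. Median depths were 4281, 2448 and 3671.5 UMIs in T and NK cells and 3026, 1773 and 4697 in B cells. Thinned to 1000 UMIs per cell, the Foxp3 shares were 2.06%, 3.20% and 4.09%, with 24, 52 and 33 cells left out, and the difference between immunotherapy and control was 2.03 points in place of 7.02.

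Transcripts of inhibitory receptors and effector molecules were read in all T and NK cells together. The make-up of these cells differed between the libraries, so the shares do not give changes within 1 class of T cell. Ctla4, which encodes a receptor that limits T cell activation, had a UMI in 8.14% of control (6.52 to 10.0), 14.2% of photon (11.8 to 16.9) and 17.3% of immunotherapy T and NK cells (15.1 to 19.7), and in 0.110%, 0.289% and 0.832% of B cells. After thinning these shares were 2.47%, 8.88% and 9.29%. Pdcd1, the gene of the PD-1 receptor, was found in 3.12%, 5.14% and 6.76% of T and NK cells and, after thinning, in 0.721%, 1.46% and 2.14%. Gzmb, the gene of the cytotoxic protease granzyme B, was found in 2.91%, 6.50% and 7.30% (thinned 1.44%, 4.37% and 3.90%). Ifng, the gene of interferon gamma, was found in 2.01%, 2.57% and 4.14% (thinned 0.412%, 1.31% and 2.51%). Lag3, Havcr2 and Tigit are receptors of restrained T cells. Lag3 was found in 1.21%, 2.17% and 4.05% (thinned 0.412%, 0.728% and 1.49%). Havcr2 was found in 0.704%, 1.76% and 2.61%, and after thinning in 0 of 971 cells, 0.582% and 0.650%. Tigit was found in 0.201%, 0.135% and 1.35%, and after thinning in 0 of 971 cells, 0 of 687 cells and 0.557%. Among the 399, 267 and 421 CD8 T cells alone, Pdcd1 was found in 4, 0 and 2 and Gzmb in 3, 0 and 3. Lag3 was found in 1, 1 and 2 of them, Havcr2 in 1, 0 and 0 and Tigit in 0, 0 and 1. The CD8 T shares were 1.75%, 2.25% and 3.56% for Ctla4 and 0.752%, 0.375% and 1.90% for Ifng. Among B cells, none of the 2733 in control had a UMI of Pdcd1, Gzmb, Havcr2 or Tigit, and the shares for Lag3 and Ifng were 0.0366% and 0.110%. Of the 691 photon B cells 0.289% had a Gzmb UMI and none a UMI of the other 5 genes. In immunotherapy B cells the shares were 0.444% for Gzmb, 0.222% each for Pdcd1 and Lag3 and 0.0555% for Tigit, with no Havcr2 or Ifng UMI in 1803 cells. Counts of 0, at 3 cells over the total, allow shares of cells with a UMI of up to 0.110%, 0.434% and 0.166% of control, photon and immunotherapy B cells, and of up to 0.309% and 0.437% of the thinned control and photon T and NK cells. In CD8 T cells of control, photon and immunotherapy the limits are 0.752%, 1.12% and 0.713%. These limits do not bound the share of cells that express a gene.

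The photon and control libraries were compared to ask what differed within each class after a 10 Gy dose. In epithelial cells, Ptgs2, the prostaglandin synthase COX-2, was 1.94-fold higher in the photon library (1.82 to 2.07) at 94.1 against 48.4 CPM. Ifrd1, a transcriptional regulator induced by stress and growth factors, was higher at 370.0 CPM (364 to 376) against 181 (176 to 186), and Ereg, which encodes the growth factor epiregulin, at 80.6 against 43.2 CPM. Epcam, an epithelial adhesion molecule, was 2.32-fold lower at 72.8 CPM (70.3 to 75.5) against 169 (164 to 174). The detoxifying enzyme gene Gsta3 was lower at a log2 ratio of -0.98, as was Gkn1, a gastric mucosal gene, at -0.90, although 1 cell held 35.8% of the control Gkn1 UMIs. Cdkn1a, the cell cycle inhibitor p21 and a target of p53, was at 67.6 CPM in photon (65.1 to 70.2) and 40.6 in control (38.1 to 43.2), and Mki67, a proliferation marker, at 80.0 and 69.0 CPM.

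Across the fixed lists in epithelial cells, 13 of 22 genes of the p53 and DNA damage response were higher in photon, with a median log2 ratio of 0.16 (-0.06 to 0.27), at percentile 99.3 of the random lists. Cdkn1a stood at 0.74, or 0.38 when each cell weighed equally, and Mdm2, the ligase that degrades p53, at 0.40, while the p53 targets Phlda3 and Zmat3 stood at -0.46 and -0.36. In epithelial cells, equal weights also count fully a low-UMI cluster of 81 control, 135 photon and 70 immunotherapy cells. Its median was 1680.5 UMIs, against 46256 in the other epithelial cluster. Of the G2/M genes 22 of 24 were higher, with a median of 0.21 (0.12 to 0.27). Ckap2 and Cenpe, which act on the mitotic spindle and the centromere, stood at 0.38 and 0.37, and Cdk1 and Tubb4b at -0.13 and -0.04. Of the S phase genes only 2 of 20 were higher, Rrm1 (0.10) and Pcna (0.05), and the median was -0.23 (-0.31 to -0.18). When each cell weighed equally this median was -0.10, Rrm1 stood at 0.23 and Pcna at 0.18, and of the G2/M genes Ckap2 stood at 0.67 and Cdk1 at -0.32. Ung, which removes uracil from DNA, stood at -0.81 and Tyms, the thymidylate synthase, at -0.39. Immediate early and dissociation stress genes were higher for 16 of 18, with a median of 0.31 (0.18 to 0.54). Egr1, an immediate early transcription factor, was at 901 against 559 CPM and the heat shock gene Hspa1a at a log2 ratio of 0.77, with 46.8% of its control UMIs in 1 cell. The heat shock genes Hsph1 and Hspa8 stood at -0.32 and -0.10.

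Interferon-response genes were modestly higher in photon epithelial cells. The interferon gamma response list had 20 of 22 members higher and a median of 0.76 (0.47 to 1.03), or 0.42 when each cell weighed equally. Iigp1, an interferon-induced GTPase, was at 7.58 against 0.408 CPM and the T cell attractant Cxcl9 at a log2 ratio of 2.26, but 1 cell held 47.3% and 41.2% of their photon UMIs and 80.0% and 100% of their control UMIs, and the ratio of Cxcl9 was 1.51 when each cell weighed equally. Ciita, the activator of MHC class II genes, stood at -0.69 and the feedback inhibitor Socs1 at -0.20. Among type I interferon response genes 17 of 24 were higher, with a median of 0.51 (0.02 to 0.73). The antiviral gene Ifit1 stood at 2.12, but at -0.67 when each cell weighed equally, and Ifi44 at 1.92 (0.16 to 4.32), and Ifi209 and Slfn5 at -1.52 and -1.38. Cd274, which encodes the ligand PD-L1, was at 1.71 against 1.51 CPM, a log2 ratio of 0.18 (-0.42 to 0.79) within counting error. MHC class II genes were lower for 11 of 13, with a median of -0.55, H2-DMb2 at -1.77 and H2-Oa at -1.53, and with H2-DMb1 at 0.88 and Ctss at 0.47, which were -0.06 and -0.70 when each cell weighed equally. B cell markers, which share these transcripts, amounted to 12.4 CPM in photon and 72.2 CPM in control epithelial cells.

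In photon macrophages, Nos2, the inducible nitric oxide synthase, was at 18.2 against 1.01 CPM (0.0255 to 5.61) in control, and the stress cytokine Gdf15 at 39.9 against 5.03 CPM. Gdf15 belongs to the p53 and DNA damage response list, of which 9 of 18 members were higher there, with a median of -0.03. The NF-kB and inflammatory list as a whole had 5 of 16 members higher and a median of -0.25 (-0.50 to 0.02). Nfkb1, a subunit of NF-kB, and the cytokine gene Il1b stood at 0.21 and 0.18, and Cxcl2 and Relb at -0.76 and -0.71. With doublets kept Il1b stood at 0.45, Cxcl2 at -0.49 and Relb at 0.08. Mitochondrially encoded genes, a sign of RNA quality, were higher for 12 of 13, with a median of 0.19. The TGF-beta list had 5 of 13 members higher and a median of -0.07. The suppressive myeloid list had 13 of 20 members higher and a median of 0.28. Its S100a9, an alarmin, stood at 2.47 with 98.0% of control UMIs in 1 cell, the cytokine Il10 at -1.52 (-0.36 when each cell weighed equally), and Retnla, a marker of alternative activation, at -3.28 (-2.34 when each cell weighed equally) with 92.0% and 98.4% of UMIs in 1 cell of each library. Hypoxia and glycolysis genes were higher for 11 of 15, with a median of 0.34, led by Egln3 (1.46) and Pdk1 (0.70), a sensor of oxygen and a switch of pyruvate use, although 1 cell held 72.2% of the control Egln3 UMIs. The type I interferon list stood at -0.84 (-1.13 to -0.44) with 1 of 25 members higher, Dhx58 at 0.32. Ifit3 was at 6.07 against 30.2 CPM and Ifit1 at a log2 ratio of -1.63. With classes taken at resolution 2, which left 82 control and 375 photon cells, this median was -0.11, Ifit1 stood at 0.14 (-1.62 to 2.24) and Ifit3 at 1.68 (-1.22 to 7.15) on 8 and 1 UMIs. The interferon gamma list had 7 of 18 members higher and a median of -0.20, with Gbp6 at 1.03, Cxcl10 at -1.71 and Cxcl9 at -2.5, the last with 58.8% of its control UMIs in 1 cell and at -1.40 when each cell weighed equally. At resolution 2 this median was 0.00 and Cxcl10 stood at 1.04 (0.20 to 1.98).

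In photon T cells, interferon-response transcripts were higher. Type I interferon genes were higher for 24 of 25 in CD4 T cells, with a median of 0.76 (0.45 to 0.95), and for 25 of 25 in CD8 T cells, with a median of 0.40 (0.21 to 0.69). Cmpk2 and Oasl2, both antiviral, were at 21.7 against 5.54 CPM in CD4 T cells, and Ifit1 at 60.0 against 18.9 CPM in CD8 T cells. The interferon gamma list had medians of 0.73 (14 of 16 higher) and 0.30 (14 of 19 higher). The type I median of CD4 T cells was 0.44 at resolution 2 and 0.43 when the interferon and MHC genes were left out of the clustering. Mitochondrially encoded genes were higher too, for 13 of 13 in CD4 T cells (median 0.44) and 13 of 13 in CD8 T cells (median 0.28), both at percentile 100 of the random lists, and epithelial markers amounted to 788 CPM in photon and 291 CPM in control CD4 T cells. Most CD4 T cells of control were in T subcluster 1 and most of photon in subcluster 6. Subcluster 6 had a median of 1883 UMIs, against 3843 in subcluster 1, and the epithelial gene Clu among its 10 leading genes. How far this difference in depth and content sets the CD4 T values was not tested. The named CD8 T genes that were higher were Krt18 (log2 1.79), S100a6 (1.73) and Krt8 (1.7), of which the keratins belong to epithelial cells, and epithelial markers amounted to 703 CPM in photon and 245 CPM in control CD8 T cells. The co-chaperone genes Stip1 (43.1 against 108 CPM) and Dnaja1 (248 against 564 CPM) and the RNA helicase gene Ddx39 (log2 -1.19) were lower. In B cells, Ier3, an early response gene, was at 68.0 against 19.9 CPM, and Krt8 and the neutrophil attractant Cxcl2 stood at 1.74 and 1.64. Epithelial markers amounted to 1004 CPM in photon and 348 CPM in control B cells. Ighg1, Slpi and Jchain had 0 UMIs in photon B cells and were at least 123-fold, 76.7-fold and 24.6-fold lower, but 1 control cell held 99.3%, 99.6% and 98.6% of their UMIs, and with each cell weighed equally the log2 bounds were -4.36, -3.66 and -2.11 in place of -6.94, -6.26 and -4.62. Cdkn1a was at 11.3 CPM in photon B cells (6.34 to 18.7) against 1.77 (1.01 to 2.88). Macrophages, a larger share of the photon library, had Cdkn1a at 769 CPM in photon and 753 CPM in control, without the cells that finer clustering moved. Myeloid markers were not read in photon B cells, so RNA from myeloid cells was not tested for Cdkn1a or Cxcl2. The all-gene median in B and in CD8 T cells lay at 0.11, and the B cell medians of the interferon gamma and type I lists were 0.18 and 0.03, beside 0.29 for the mitochondrially encoded genes.

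Photon neutrophils had higher levels of the epithelial genes Emp1 (58.0 against 11.7 CPM), Wfdc2 (115 against 26.3 CPM) and Clu (684 against 197 CPM). Epithelial markers amounted to 1207 CPM in photon and 417 CPM in control neutrophils. The B cell genes Igkc, Ly6d and Cd79b were lower at log2 ratios of -3.67, -3.44 and -3.18, where all B cell markers amounted to 130.3 CPM in photon and 1019 in control. With called doublets kept these ratios were -2.67, -1.90 and -1.41, and that of Cd79b was -2.36 when each cell weighed equally. The interferon gamma and type I interferon medians of neutrophils were 0.13 and 0.00.

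The immunotherapy and control libraries were compared to ask what differed within each class after combination immunotherapy. Interferon-response list medians were above 0 in all 7 classes compared, highest in epithelial cells and, for the interferon gamma list, lowest in Treg cells. In epithelial cells Iigp1 was at 92.1 CPM (87.7 to 96.7) against 0.408 in control (0.196 to 0.750), 226-fold higher with a counting interval from 123 to 472, and 1 cell held 80.0% of the 10 control UMIs. Igtp, another interferon-induced GTPase, was at 129 CPM (124 to 135) against 2.77 (2.15 to 3.52), a log2 ratio of 5.54, or 4.63 when each cell weighed equally. Cxcl9 was at 52.3 CPM (48.9 to 55.8) against 1.10 (0.726 to 1.6), with 34.5% of the immunotherapy UMIs and 100% of the control UMIs in 1 cell, and its log2 ratio of 5.57 was 4.85 when each cell weighed equally. Cd274 was at 8.85 CPM (7.51 to 10.4) against 1.51 (1.06 to 2.08), and Ido1, which degrades tryptophan, at 39.0 against 0.693 CPM. The gastric-type genes Tff2 (522 against 1036 CPM) and Gkn3 (215 against 390.4 CPM) and Gsta3 (60.5 against 126 CPM) were lower. Cdkn1a and Mki67 stood at log2 ratios of 0.26 and -0.02.

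**Figure D2:**
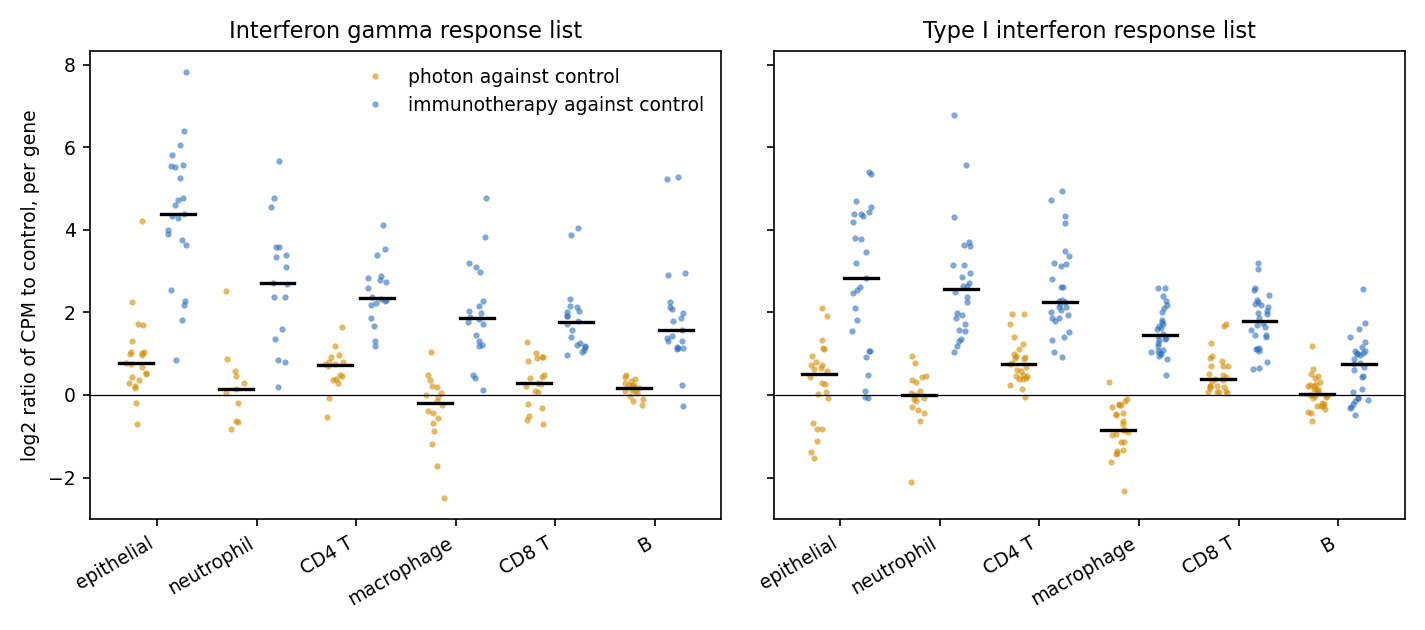
Log2 ratio of CPM to control for each member of the interferon gamma response list (left) and the type I interferon response list (right) in 6 cell classes; points are genes, orange for photon and blue for immunotherapy, and black bars are medians. Immunotherapy medians run from 1.58 in B cells to 4.37 in epithelial cells on the left, and the photon macrophage median lies at -0.84 on the right.

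In epithelial cells all 23 measured interferon gamma response genes were higher in immunotherapy, with a median log2 ratio of 4.37 (3.89 to 5.25) at percentile 100 of the random lists. The highest were Iigp1 and the GTPase gene Tgtp2 (6.39), and the lowest Socs1 (0.84) and the protease inhibitor gene Serpina3g (1.81). Of the type I interferon genes 25 of 27 were higher, with a median of 2.84 (1.81 to 4.19). Ifit1 stood at 5.41 and the ubiquitin-like Isg15 at 89.9 against 2.20 CPM, while Slfn5 and Slfn8 stood at -0.08 and -0.04. MHC class I presentation genes were higher for 17 of 20, with a median of 1.27 (1.06 to 1.56). Nlrc5, the activator of MHC class I genes, stood at 3.89, the peptide transporter gene Tap1 at 20.5 against 1.51 CPM, and the chaperone genes Pdia3 and Canx at -0.09 and -0.05, each of which turned positive under 1 other scaling. With each cell weighed equally Tgtp2 stood at 4.25, Serpina3g at 4.59, Ifit1 at 2.77, Nlrc5 at 5.01 and Tap1 at 2.39 in place of 3.76. MHC class II genes were higher for 11 of 13, with a median of 0.93 (0.21 to 1.47), H2-DMb1 at 2.79 and Ciita at 2.18 (1.79 and 1.54 when each cell weighed equally), and with H2-Ob at -0.64 and Lgmn at -0.04. B cell markers in epithelial cells were at 73.9 CPM in immunotherapy and 72.2 CPM in control. Hypoxia and glycolysis genes were higher for 15 of 15 with a median of 0.29 (0.24 to 0.49), from Gapdh (0.12) and Ldha (0.18) to Ndrg1 and the glucose transporter gene Slc2a1 (both 0.56, with Ndrg1 at 0.86 when each cell weighed equally).

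T cells of the immunotherapy library had the same lists higher. In CD4 T cells the interferon gamma median was 2.35 (2.20 to 2.80; 18 of 18 higher) and the type I median 2.25 (2.01 to 2.81; 29 of 29 higher). Iigp1 was at 344 CPM (308 to 382) against 19.7, the guanylate-binding protein gene Gbp2 at 297 against 25.9 CPM, and Ifi44 and Ifit3b stood at 4.93 (2.98 to 8.03) and 4.73 (2.76 to 7.83). The lowest interferon gamma members were Irf1 (1.19) and Nlrc5 (1.31). Ctla4 was at 18.8 CPM (11.3 to 29.3) in immunotherapy CD4 T cells against 2.46 (0.671 to 6.30). CD8 T cells had an interferon gamma median of 1.75 (1.23 to 2.02; 20 of 20 higher) and a type I median of 1.79 (1.45 to 2.16; 28 of 28 higher), with Iigp1 at 135 CPM (118 to 153) against 9.18 (5.44 to 14.5) and Oasl2 at 65.1 against 7.14 CPM. Cd274 was at 63.4 CPM (52.3 to 76.2) against 14.3 (9.49 to 20.6) in CD8 and at 54.3 against 11.1 CPM in CD4 T cells. Cytotoxic effector genes of CD8 T cells were higher for 12 of 15 with a median of 0.32, led by Gzma (3.45, 1.41 to 6.59), another granzyme gene, and Gzmb (15.6 against 3.06 CPM, with 85.7% of UMIs in 1 cell), while the chemokine gene Ccl5 was lower at 303 against 709 CPM and the receptor gene Cxcr3 stood at -0.23. Kidins220, a membrane scaffold gene, and the immediate early gene Fos were lower at -1.22 and -1.12, and Hspa1a stood at 5.43 with 89.9% of its UMIs in 1 cell. Most immunotherapy CD8 T cells lay in T subcluster 2 and CD4 T cells in subcluster 4, both led in part by interferon genes, and most control cells in subclusters 0 and 1. Mitochondrially encoded genes stood at medians of 0.16 in CD4 and 0.11 in CD8 T cells. When the interferon and MHC list genes were left out of the clustering, an alternative added after the data were seen, the interferon gamma medians were 1.68 in CD8 and 2.33 in CD4 T cells.

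Treg cells of the immunotherapy library differed from those of control in effector and receptor genes. The class is 1 T subcluster, with Cd4 detected in 51.25% of its cells and Cd8a or Cd8b1, whichever was more frequent, in 14.7%. At resolution 2 the Treg share of T and NK cells was 9.41% in immunotherapy and 3.03% in control, in place of 18.6% and 7.74%. The values below therefore rest in part on cells that lose the name there. Interferon gamma genes were higher there for 17 of 19 (median 0.73, 0.42 to 1.41), with Cxcl10 at 4.72 (2.19 to 10.04) on 1 control UMI, Gbp6 at 2.01, Cd274 at -0.42 and Socs1 at -0.04. Type I genes were higher for 24 of 27 (median 0.96, 0.60 to 1.33), with Ifit3 at 2.24, Oasl2 at 2.07 (0.06 to 5.2) on 2 control UMIs, Ifi208 at -0.80 and Ifit2 at -0.51. The regulatory T list had 18 of 20 members higher, with a median of 0.48, among them Icos, a co-stimulatory receptor, at 925 CPM (868 to 985) against 431 (367 to 504) and the cytokine Il10 at a log2 ratio of 2.88 (0.24 to 8.25). Areg, which encodes the tissue repair factor amphiregulin, was lower at -2.22, or -0.0035 when the interferon and MHC genes were left out of the clustering, and the interleukin 33 receptor gene Il1rl1 stood at -0.30. Ctla4 was at 502 CPM (460.3 to 547) against 283 (232 to 343), Lag3 at 44.4 (32.7 to 59.1) against 16.2 (5.94 to 35.2) and Pdcd1 at 96.4 against 56.6. Foxp3 itself was at 229.8 against 213 CPM, a log2 ratio of 0.11 (-0.26 to 0.49) within counting error. Co-inhibitory genes were higher for 8 of 10, with a median of 0.80, led by Cd160 (1.59) and with Btla at -0.64 and Cd200 at -0.54. All 15 measured S phase genes were higher, with a median of 1.30 (1.07 to 1.49), with Pcna lowest at 0.39. Mki67 was at 33.1 CPM (23.1 to 46.0) against 35.1 (18.7 to 59.9) in the same Treg cells, a log2 ratio of -0.08 (-1.04 to 0.96), and cells led by proliferation genes formed a cluster outside this class. Chaf1b and Uhrf1, both of chromatin during replication, stood at 2.81 (0.17 to 8.18) and 2.91 (0.97 to 6.01). Gzmb was lower at 122 against 259 CPM, with 53.1% of its control UMIs in 1 cell, and its log2 ratio of -1.09 was -0.57 with doublets kept.

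In B cells of the immunotherapy library, the named genes Klf2, Abca1 and Rflnb were lower. Klf2, a transcription factor of quiescence and trafficking, was at 59.2 CPM (54.4 to 64.4) against 696 (678 to 713), 11.7-fold lower. S1pr1, the receptor for leaving lymph nodes, was at 11.4 against 104 CPM. Both belong to the naive T list, which was not set for B cells and had 9 of 11 members lower (median -1.29, -1.80 to -0.43), with Lef1 at 0.60 and Tcf7 at 0.04. The cholesterol exporter gene Abca1 was at 7.31 against 124 CPM and the filamin-binding Rflnb at 6.13 against 66.0 CPM. Interferon gamma response genes were higher for 20 of 21, with a median of 1.58 (1.31 to 2.08). Iigp1 stood at 5.22 (3.32 to 8.29) and the chemokine gene Cxcl10 at 13 against 0 CPM, and Ciita and Cd274 at -0.27 (-0.14 with size factors) and 0.25 (0.50 when each cell weighed equally). Type I genes were higher for 21 of 29 (median 0.75, 0.15 to 1.03), with Isg15 at 150.4 against 25.5 CPM, Oas1a at 1.73, Ifit3b at -0.48 and Irf7 at -0.31. S phase genes were higher for 18 of 19 (median 0.93, 0.54 to 1.28), led by Uhrf1 (1.99) and the helicase gene Mcm5 (1.37), with Slbp at -0.31 and Pcna at 0.41. The antibody heavy chain genes Ighg2c (460.1 against 0.111 CPM, a log2 ratio of 12.02 with an interval from 9.54 to 17.32) and Ighg2b (648 against 1.66 CPM) were higher, with 56.8% and 37.4% of UMIs in 1 cell. The haemoglobin gene Hbb-bs was at least 470.4-fold higher, with 99.8% of UMIs in 1 cell. Control B cells lay mostly in cluster 0 and immunotherapy B cells in clusters 2 and 7, and the all-gene median in B cells was -0.14.

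Neutrophils and macrophages of the immunotherapy library carried the interferon lists as well. In neutrophils all 17 interferon gamma genes were higher (median 2.71, 1.59 to 3.57), with Cxcl10 (0.20) and Socs1 (0.81) lowest. Gbp5 led at 5.67 (3.13 to 11.00), before Gbp3 at 4.76 (2.85 to 7.84), and Iigp1, with 0 control UMIs, entered the median at its bound. All 26 type I genes were higher there too (median 2.56, 1.90 to 2.95), beside a median of 0.22 for the mitochondrially encoded genes. Ifit1 was at 108 CPM (89.7 to 129) against 0.976 (0.0247 to 5.44). Ly6c2, a surface antigen gene of the monocyte marker list, was at 143 against 4.88 CPM. Mmp8, a granule collagenase gene of the neutrophil marker list, was at 98.3 against 3.90 CPM. Monocyte RNA in the neutrophil class was not measured. With doublets kept the log2 ratio of Ly6c2 was 3.52 in place of 4.87. The small GTPase gene Rap2a, the Mediator subunit gene Med21 and the nuclear receptor gene Nr4a2 were lower at -1.30, -1.25 and -1.12. Cd274 was at 389.7 against 218 CPM in neutrophils. Macrophages had all 20 interferon gamma genes higher (median 1.85, 1.37 to 2.22), with Iigp1 at 83.0 against 3.02 CPM, Serpina3g at 3.83, Ciita at 0.11 and Cd274 at 0.40, and all 28 type I genes (median 1.45, 1.25 to 1.71). Finer clustering moved 26 of 80 macrophages in immunotherapy and 9 of 91 in control to other classes. The moved immunotherapy cells had Ly6c2 at 3605 CPM and C1qa, a macrophage complement gene, at 52.7 CPM. The immunotherapy cells left had these genes at 47.1 and 2976 CPM. Without the moved cells, the interferon gamma and type I medians were 1.62 and 1.48, with 16 of 18 and 21 of 21 genes higher. Iigp1 was then at 43.3 against 3.30 CPM, a log2 ratio of 3.72 (1.99 to 6.09) on 3 control UMIs in place of 4.78, and Ciita and Cd274 stood at -0.30 (-0.99 to 0.36) and 0.09 (-0.43 to 0.59), so neither direction was resolved. Of the suppressive myeloid list 7 of 19 were higher, with a median of -0.36, or -0.07 (-0.90 to 0.22) without the moved cells. Wfdc17, a macrophage secreted inhibitor, was at 261 against 728 CPM. Retnla had 0 UMIs against 583 CPM, of which 98.4% came from 1 control cell, and its log2 bound of -7.20 was -6.29 when each cell weighed equally, while S100a8 and S100a9 stood at 2.52 and 1.73, the former with 54.9% and 96.7% of UMIs in 1 cell of each library. Most control UMIs of S100a9 lay in 1 cell too, as given above for the photon comparison.

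**Figure D3:**
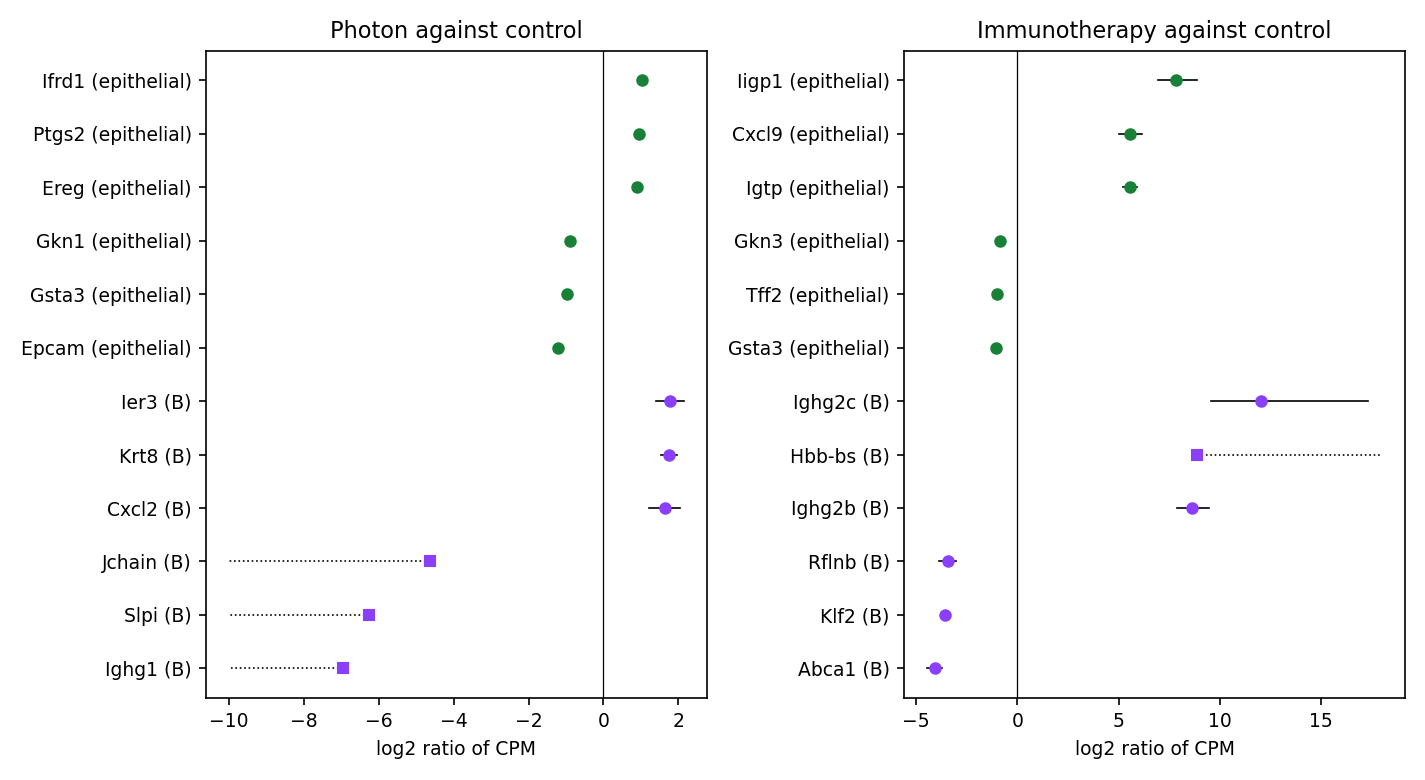
Log2 ratio of CPM for the named genes of epithelial cells (green) and B cells (purple), photon against control at left and immunotherapy against control at right; circles are ratios with lines for 95% counting intervals, and squares with dotted lines are bounds where 1 library had 0 UMIs. Iigp1 in epithelial cells lies at 7.82 and Klf2 in B cells at -3.55 for immunotherapy, while Epcam in epithelial cells lies at -1.21 for photon.

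The immunotherapy and photon libraries were compared directly to ask how the treatments differed, without the control library. In epithelial cells, the interferon-induced GTPase genes Gbp3 (68.1 CPM, 64.3 to 72.1, against 2.85, 2.36 to 3.42), Igtp (129 against 5.41 CPM) and Gbp2 (220.1 against 9.85 CPM) were 22.4 to 23.9 times as high in immunotherapy. Inhba, a subunit of the growth factor activin, was lower at 19.8 against 53.2 CPM, Ptgs2 at 36.9 against 94.1 CPM, and Cym, the gene of the digestive protease chymosin, at 22.3 against 50.1 CPM. Cd274 was at 8.85 against 1.71 CPM, and Cdkn1a stood at -0.48, or -0.20 when each cell weighed equally. All 23 interferon gamma genes were higher, with a median of 3.55 (3.30 to 4.04), from Socs1 (1.04) and Irf1 (1.93) to Ido1 (4.81) and Tgtp1 (5.03). All 25 type I genes were higher, with a median of 2.51 (2.11 to 3.05), with Zbp1, a sensor of nucleic acids, at 4.04, or 3.20 when each cell weighed equally. MHC class I genes were higher for 19 of 20 (median 1.24) and MHC class II genes for 13 of 13 (median 1.54), the latter beside B cell markers at 73.9 CPM in immunotherapy and 12.4 CPM in photon. S phase genes were higher for 19 of 20, with a median of 0.30 (0.22 to 0.40). Of the TGF-beta list 2 of 14 were higher, with a median of -0.29.

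Macrophages of the immunotherapy library had all 20 interferon gamma genes higher than photon (median 2.60, 1.46 to 3.01), with Iigp1 at a log2 ratio of 5.00 (3.79 when each cell weighed equally) and Cxcl9 at 629 CPM (574 to 688) against 30.3 (23.6 to 38.3), and all 28 type I genes higher (median 2.5). Of their suppressive myeloid list 6 of 21 were higher, with a median of -0.54. Spp1, which encodes the matrix protein osteopontin, was at 244 CPM (210.0 to 282) against 1738 (1685 to 1793). Of the TGF-beta list 1 of 12 members was higher, with a median of -0.50. These values rest in part on cells that finer clustering moved to other classes, 26 of 80 in immunotherapy and 6 of 381 in photon, in which C1qa, a macrophage complement gene, was at 52.7 and 87.0 CPM against 2976 and 2533 CPM in the cells left. Without the moved cells the medians were 1.85 for the interferon gamma list (1.07 to 2.35; 17 of 19 higher), 1.73 for the type I list (1.39 to 1.86; 24 of 24 higher), -0.20 for the suppressive list (-0.74 to 0.19) and -0.29 for the TGF-beta list, and Iigp1, Cxcl9 and Spp1 stood at log2 ratios of 4.04, 3.76 and -2.5. The interferon gamma medians were 1.14 in B cells, 1.42 in CD8 T cells, 1.56 in CD4 T cells and 2.62 in neutrophils, and the type I medians 0.65, 1.30, 1.45 and 2.67. Mitochondrially encoded genes stood at medians of -0.28, -0.16, -0.24 and 0.15 in these classes and -0.16 in macrophages.

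Among the other named genes of this comparison, the B cell heavy chain genes Ighg2b, Ighg2c and Ighg1 were higher in immunotherapy, the first by 8.74 on the log2 scale (6.89 to 11.79) and the others by at least 203-fold and 155-fold, with 37.4%, 56.8% and 51.6% of UMIs in 1 cell. With each cell weighed equally the log2 ratios of Ighg2c and Ighg1 were 6.43 and 6.29 in place of 7.67 and 7.28. In B cells, Abca1 (7.31 against 107 CPM), the complement regulator gene Cd55 (54.4 against 554 CPM) and Klf2 (59.2 against 568 CPM) were lower. Cd55 is among the 10 leading genes of cluster 0, which held most photon B cells, and the all-gene median in B cells was -0.23. In CD8 T cells Igkc was at 123 against 1.30 CPM, with a log2 ratio of 6.56 (4.07 to 11.87) that was 3.79 when the interferon and MHC genes were left out of the clustering, and Ly6a, an interferon-inducible surface antigen, at 287 against 41.8 CPM. Hspa1a stood at 3.49, with 89.9% of UMIs in 1 cell, and the epithelial genes Krt8, Clu and Krt18 at -1.96, -1.92 and -1.73, beside epithelial markers at 191 CPM in immunotherapy and 703 CPM in photon. In neutrophils the interferon-induced GTPase gene Ifi47 was at 129 against 4.74 CPM, the B cell genes Fcer2a and Ms4a1 stood at 5.07 and 4.52, and Wfdc2, Clu and Emp1 at -2.59, -2.23 and -2.06. The B cell markers in neutrophils were at 1172 CPM in immunotherapy and 130.3 CPM in photon, and with doublets kept Fcer2a and Ms4a1 stood at 3.69 and 2.53. The epithelial markers there were at 301 and 1207 CPM, and the ratio of Clu was -1.58 when each cell weighed equally.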

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

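The tests of scaling, of single libraries, of the mixture of tumour and node cells, of the cell filters and of the cells in the macrophage class were chosen only after the result was seen, while the test of RNA from other cells was not.

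The share of barcodes over the mitochondrial limit, which the comparisons leave out, was above control in both treated libraries, at 32.1% in photon (30.9 to 33.2) and 31.6% in immunotherapy (30.5 to 32.8) against 20.6% in control (19.6 to 21.6). When all barcodes were clustered and named together, 32.9% of these barcodes were epithelial and 10.0% B cells in photon. The shares were 20.1% and 36.1% in control, and 15.1% and 46.3% in immunotherapy.

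The median of the type I interferon list for photon against control had opposite signs in macrophages (-0.84) and in epithelial cells (0.51), and the difference was not tested. As to the macrophage value, another scaling is argued against, since over the other scalings the median nearest 0 was -0.59 (-1.21 to -0.43). Depth was not equalised in these scalings and was not tested. A few cells of the class may account for most of the macrophage value, but they are not shown to be another kind of cell. Finer clustering moved 9 of 91 control, 6 of 381 photon and 26 of 80 immunotherapy macrophages to other classes, 29 of the 30 control Ifit3 UMIs lay in the moved cells, and without them the median was -0.11 (-0.28 to 0.04). The moved control cells had C1qa, a macrophage complement gene, at 1169 CPM, against 2807 CPM in the control cells left. Interferon genes were not left out of this clustering, so it could also have set apart interferon-high macrophages. An effect of photons on the macrophages stays open and untested.

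Interferon-response genes were higher in the immunotherapy library in the 6 classes with enough cells in all 3 libraries, to which the tests below apply, while Treg cells were left out of them. For the interferon gamma list, RNA or attached cells of the B, epithelial, neutrophil, macrophage and T classes are argued against as the whole cause, except in neutrophils. The share of other cells' RNA needed to give the list's level was at least 1.39 times the share read from the markers of these classes. This ratio was lowest in neutrophils (35.8% needed, 25.8% read) and 7.40 to 23.5 in the other 5 classes. It has no interval, and the needed share was computed from the mean level of the highest other class. Cells above that mean would lower it, so for neutrophils the test does not decide. Monocyte and dendritic cell markers were not part of the share read, so this test does not exclude such cells within the macrophage class. Of the immunotherapy macrophages, finer clustering moved 26 of 80, with Ly6c2, a gene of the monocyte marker list, at 3605 CPM against 47.1 CPM in the cells left. Their C1qa was at 52.7 CPM against 2976 CPM. By these genes the moved cells were nearer to monocytes than the cells left were. Without the moved cells of both libraries the macrophage median was 1.62 (0.65 to 2.61). Scaling is argued against too for this list, as the lowest interferon gamma median under any other scaling was 1.62 (1.36 to 2.16), in B cells. None of these scalings equalised the depth of the cells, so depth was not tested. For the type I list, RNA from other cells was not tested and stays open, and its lowest median under the other scalings was 0.80, also in B cells. With 1 pooled library per group, a difference between these pools unrelated to the immunotherapy cannot be told apart from the treatment, which stays open.

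B cells were a lower share of cells in the photon library than in control. Another proportion of tumour to lymph node cells is argued against as the whole cause, since B cells per CD4 or CD8 T cell with a Ccr7 or Lef1 UMI, as T cells of lymph nodes carry, were 3.89 in control (3.58 to 4.24) and 1.80 in photon (1.59 to 2.05), a ratio of 2.16. The cell filters are argued against by the difference with all barcodes, -38.3 percentage points. The mixture can still set part of the share, and an effect of photon irradiation on node B cells and a difference between single pools both stay open.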

How the results depend on the processing

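The settings with at most 20% mitochondrial UMIs, without an epithelial cluster of low UMIs, and with clustering without interferon and MHC genes were chosen after seeing the data, and all others were planned. No paired analysis was possible because each group has 1 library. For the genes with the highest and lowest ratios in a class, 395 of 432 values under alternatives stayed within counting error, 37 moved and 0 changed sign. For the other named genes, 1422 of 1515 stayed, 83 moved and 10 changed sign against a counting interval that left out 0, and 1471 kept their direction. The 10 were Ifit1 (-0.67), H2-DMb1 (-0.064) and Ctss (-0.70) of photon and Pdia3 (0.072) of immunotherapy epithelial cells when each cell weighed equally, Canx of the latter (0.011) with size factors, Relb in photon macrophages (0.079) with doublets kept, and at resolution 2 Cxcl10 (1.04), Ifit3 (1.68) and Ifit1 (0.14) in photon macrophages and Chil3 in macrophages of immunotherapy against photon (-0.20). Of 222 list medians 214 stayed within their interval, 8 moved and 221 kept their direction, and of 134 shares and share differences 101 stayed, 28 moved and 119 kept their direction. Apart from the test of the cells in the macrophage class given above, the cause was not tested where values moved or reversed.

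Share differences from control follow in percentage points. The photon Treg difference of -2.87 reversed with 4000 variable genes (7.32), classes by marker score (4.83), doublets kept (7.69), resolution 2 (5.86) and the stricter filter (14.6). For immunotherapy the Treg difference of 10.9 was 6.38 at resolution 2 and 16.3 under the stricter filter. The photon macrophage difference of 7.38 was 8.60 with 4000 variable genes, 8.54 with doublets kept, 8.51 at resolution 0.5, 8.59 with all barcodes, 8.89 at 20% mitochondrial UMIs, 8.67 under the stricter filter and 4.77 by marker score. With all barcodes, B cells were at -38.3 in photon and -8.61 in immunotherapy (-41.2 and -14.2 as reported), T and NK cells at -5.48 and 2.22 (-3.10 and 5.89), and neutrophils at 10.9 and 1.79 (16.4 and 3.54). At 20% mitochondrial UMIs the immunotherapy B difference was -11.5 and the photon neutrophil difference 14.2. Thinning gave 14.8 for photon neutrophils and 2.03 for the share of immunotherapy T and NK cells with a Foxp3 UMI (7.02 as reported). Marker scores gave -37.2 and -11.3 for B cells, 13.9 for photon epithelial cells (16.1 as reported) and 13.2 for photon neutrophils. The stricter filter gave -45.6 for photon B cells, -6.97 and 3.37 for T and NK cells, and 23.3 and 4.77 for neutrophils.

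Among list medians, classes from resolution 2 gave 1.86 for the type I list in CD4 T cells of immunotherapy (2.25 as reported), -0.11 in photon macrophages (-0.84), 1.73 in macrophages of immunotherapy against photon (2.5) and 0.44 in photon CD4 T cells (0.76), and left too few Treg cells for a median. Clustering without interferon and MHC genes gave 0.43 for the type I list in photon CD4 T cells. The mean over cells gave 1.21 for the type I list in immunotherapy macrophages (1.45), and in photon epithelial cells 0.42 for the interferon gamma list (0.76) and -0.10 for the S phase list (-0.23). Depth limits the photon B cells (median 1773 UMIs) and the macrophages of control and immunotherapy (91 and 80 cells), where genes under 100 UMIs have intervals wider than 21.6%, and the Treg cells of photon (36 cells), which were too few for a comparison of levels.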

Other observations

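The test of further chaperone genes was chosen only after the result was seen, and the test of further sterol genes was not.

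Cycling lymphocytes, a cluster led by proliferation genes, were 4.92% of immunotherapy cells (4.28 to 5.63) against 0.489% in control (0.310 to 0.733) and 0.562% in photon (0.357 to 0.842). Of the 202 such cells in immunotherapy, 96 had more T than B transcripts, 104 more B than T transcripts, and 56 had a Foxp3 UMI, while of the 23 in control 16 had more T transcripts and 10 a Foxp3 UMI. In immunotherapy B cells, the NF-kB and inflammatory list had 11 of 15 members higher than in control, with a median log2 ratio of 0.46, led by the anti-apoptotic genes Bcl2a1d (229 against 16.2 CPM) and Bcl2a1b (3.10), and with the chemokine genes Ccl2 and Cxcl1 at -1.01 and -0.79. Immediate early genes were lower there for 14 of 18, with a median of -0.81, Dusp1 at -1.93 and Fos at -1.88. Antigen-presenting co-stimulation genes were higher for 7 of 11 and lower for 4, with the cytokine gene Il15 at 2.76 and Ccr7, which guides cells into the T zone, at -1.77.

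Migratory dendritic cells were 0.723% of control, 1.20% of photon and 1.41% of immunotherapy cells, and cDC2 cells 0.872%, 2.00% and 0.682%. NK cells were 0.804%, 1.89% and 2.25% of T and NK cells, and gamma-delta T cells 1.41%, 0.541% and 1.08%. CD8 T cells numbered 1.02, 1.08 and 1.37 per CD4 T cell, and Treg cells 0.197 (0.152 to 0.252), 0.145 (0.0994 to 0.206) and 0.674 (0.563 to 0.807). The photon Treg number depends on the clustering, as given above.

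In B cells of the immunotherapy library, the sterol genes Idi1, Fdps and Cyp51 were noticed at 79.7 against 14.0, 70.2 against 14.98 and 64.3 against 15.6 CPM in control. The hypothesis that sterol synthesis was higher as a whole was tested on 19 further genes of the pathway. Of these, 18 were higher than in control, with a median log2 ratio of 1.06 (0.71 to 1.42) at percentile 100 of the random lists, and the median against photon was 0.83. The values are consistent with a higher sterol programme in these B cells, whose S phase list was higher too, and no replicate bears on it.

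In CD8 T and B cells of the photon library, the chaperone genes Hsph1, Dnaja1, Dnajb1, Stip1 and Ahsa1 were noticed to be low. The hypothesis that chaperones were lower as a group in lymphocytes was tested on further chaperone genes. Their medians were -0.29 in CD8 T cells, -0.22 in CD4 T cells and -0.19 in B cells, at percentiles 0.00, 0.13 and 0.03, with 17 of 20, 14 of 20 and 16 of 22 members lower, against -0.04 in epithelial cells, -0.04 in neutrophils and -0.08 in macrophages. In immunotherapy against control the list stood at 0.42 in B cells (0.11 to 0.55, percentile 99.98), -0.06 in CD8 T cells and -0.01 in CD4 T cells, so the direction differed between the treated libraries in B cells, which was not tested. Mitochondrially encoded genes were higher in the same photon lymphocytes, with medians of 0.28, 0.44 and 0.29, and epithelial markers amounted to 703, 788 and 1004 CPM against 245, 291 and 348 in control. Freezing, thawing and dissociation also act on these genes, and since each group was handled as 1 pool, handling may differ with the group.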
